A study of Gallus gallus with 4 samples.

How the data were processed

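Small RNA of chicken cecum was profiled in 4 libraries, 2 from birds inoculated with Campylobacter jejuni and 2 from non-infected birds. Per the labels' protocols, RNA was extracted with Trizol, a gel fraction of 18 to 38 nt was taken, and adapters were ligated to both ends before reverse transcription and PCR. The deposited files list, for each library, every distinct read sequence (tag) and its whole-number count, with no normalization and no miRNA name. The tags were 15 to 50 nt long. The submitters' processing notes name the genome build galGal4; the trimming tool, the aligner and any filter on tags are not given in the sources used here. Whole-number counts with different totals per library were taken as raw read counts.

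Because the files name no miRNA, tags were named here. Mature sequences of 144 conserved miRNAs, 6 tRNA 5′ ends and 2 rRNAs were written down from general knowledge before the tags were tabulated. A tag of 18 to 26 nt was given to a miRNA when its first 18 bases were identical to that sequence, the longest shared start deciding between candidates; 22 tags with a tie were left out. Of the 144 sequences, 132 had at least 1 matched read and 127 were seen exactly as written. In the RefSeq gene table of assembly GRCg7b, used for names only, 132 of the 144 had a chicken miRNA gene. The planned match to annotated hairpins was not made, as no hairpin or genome sequence was used here. Names thus rest on conserved sequences and not on a chicken reference. Genes with the same mature sequence cannot be told apart, and close relatives (let-7a and let-7c, miR-18a and miR-18b, miR-27a and miR-27b, miR-30b and miR-30c, miR-103 and miR-107, miR-133a and miR-133b, miR-146a and miR-146c) are uncertain. Tags given to no miRNA were tested only in tag groups. These groups held all tags of at least 18 nt by their first 18 bases, miRNA tags included.

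Counts per miRNA were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10, TMM factors, glmQLFit with robust dispersion and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 4 libraries left 2 residual degrees of freedom, to which edgeR added a median of 7.30 prior degrees, and the common biological coefficient of variation was 0.219. Standard errors of log2 fold changes were derived from the F statistic. Lists of miRNAs were tested with camera (preset correlation 0.01, and estimated) and fry of limma 3.58.1, and arm usage with diffSpliceDGE for hairpins with both arms past the filter. CPM are read counts scaled to a common library size and normalized by TMM. Tables were built in Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1, and figures in matplotlib 3.10.9. The test was run on 20 sets of simulated counts for the 117 miRNAs, in which it called 19 of 1860 unchanged miRNAs (1.02%). These false calls stood beside 18, 67 and 151 calls in the right direction among miRNAs changed 1.5-fold, 2-fold and 4-fold.

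Total counts ranged from 14960925 to 18662264 reads per library. A count of 3 corresponded to between 0.167 and 0.215 CPM of miRNA reads; such floors, and exact binomial intervals at 95%, cover counting error only, since PCR reads are not independent molecules. Chi-square statistics between pairs of libraries, from 508 to 3941 per degree of freedom, were all far above sampling noise, so that the 4 libraries were counted separately.

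The comparison, the lists, the rule for named miRNAs and most alternatives were fixed before the data were examined. Named miRNAs were the 5 with the smallest unadjusted p in each direction at a mean of at least 10 CPM (no miRNA having passed the threshold), the 5 most abundant, the 3 most abundant tested members of each list, the 3 hairpins with the smallest arm-usage p, and the single-hairpin entries miR-126, miR-210 and miR-2954. The lists covered immune response, leukocytes, red cells, intestinal epithelium, smooth muscle and stroma, striated muscle, endothelium, nervous tissue, liver and pancreas, the let-7, miR-17-92, miR-34 and miR-30 families, hypoxia and sex bias. Alternatives were RLE factors, library totals, upper-quartile factors, no count filter, a filter at 10 CPM, a replicate block, each library left out, DESeq2 1.42.0, limma-voom, edgeR's exact test, sums over miRNAs sharing their first 18 bases, a threshold of 0.1 and, for composition, all tags or tags with at least 10 reads. A pseudocount alternative did not apply to counts. Added after the data were seen were exact mature sequences only, a 5′ shift of up to 2 bases, the crossed pairing as block and the tag groups. Conserved sites of bacterial 16S rRNA, matched over 14 bases and given as counts only, were also added then. The other splits of the 4 libraries and the shares of reads at other 5′ starts were not in the plan fixed beforehand.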

Results

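Small RNA was sequenced from the cecum, the blind pouch at the end of the avian small intestine, of specific-pathogen-free Leghorn chickens. In the infected group, birds had received an inoculum of 8 log10 colony-forming units of Campylobacter jejuni, a bacterium that colonizes the poultry gut and causes food-borne enteritis in people. The labels gave 2 libraries per group, 4 in all, and the comparison asked which microRNAs (miRNAs, RNAs of about 22 nt that repress messenger RNAs) differed after infection. The groups were housed in separate incubators, so that infection and housing went together. Total counts were 18662264 reads in non-infected 1, 14960925 in non-infected 2, 15293889 in infected 1 and 15376523 in infected 2. Tags matched to a miRNA held 96.0%, 93.2%, 93.8% and 95.2% of these reads in the same order.

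The cecum of both groups was dominated by a few miRNAs of the gut epithelium and gut wall. The most abundant was miR-215 (ATGACCTATGAATTGACAGAC), an intestinal epithelial miRNA, at 390970 ± 74730 CPM (normalized read count as a share of all miRNA reads; mean ± SD, n = 2) without infection and 373382 ± 68489 CPM with it. It was followed by miR-143 (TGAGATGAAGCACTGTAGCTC), a smooth muscle miRNA, at 316149 ± 31019 and 336672 ± 26670 CPM. Below these came miR-10b (TACCCTGTAGAACCGAATTTGT), miR-26a (TTCAAGTAATCCAGGATAGGC) and miR-22-3p (AAGCTGCCAGTTGAAGAACTGT), with 59598 ± 22060, 27499 ± 54.7 and 23102 ± 1026 CPM in non-infected libraries. In infected libraries the same miRNAs stood at 58133 ± 14899, 23725 ± 1495 and 21822 ± 1277 CPM. The fifth place of miR-22-3p held for the mean of all libraries; miR-21 was above it in infected libraries, at 22871 ± 242 CPM, and below it in non-infected libraries, at 22046 ± 133 CPM. Each library's own 5 most abundant miRNAs, with miR-21 in place of miR-22-3p in both infected libraries, took 83.2% and 79.8% of miRNA reads in the non-infected libraries and 79.9% and 82.7% in the infected libraries. None of miR-215, miR-143, miR-10b, miR-26a and miR-22-3p was called between the groups by edgeR's quasi-likelihood test, with log2 fold changes from −0.21 to 0.091 and Benjamini-Hochberg adjusted p from 0.836 to 0.947.

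Infected and non-infected cecum were not distinguished at any single miRNA. The miRNAs nearest to a difference on the higher side were miR-146c, of a family that restrains innate immune signalling, then miR-182 and miR-146a, and on the lower side miR-204 and the epithelial miR-200b. miR-146c (TGAGAACTGAATTCCATGGACTG) averaged 2865 ± 49.4 CPM in non-infected and 3799 ± 108 CPM in infected libraries (mean ± SD, n = 2), a log2 fold change of 0.41 ± 0.14 (SE). miR-204 (TTCCCTTTGTCATCCTATGCCT) averaged 35.1 ± 3.93 and 22.7 ± 1.36 CPM, a log2 fold change of −0.63 ± 0.23. Both had an edgeR adjusted p of 0.746.

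Of 117 miRNAs tested with edgeR, 0 were called higher and 0 lower at an adjusted p threshold of 0.05, and the smallest adjusted p was 0.746. At an unadjusted p under 0.05 there were 7. DESeq2 called 0, with 7 at an unadjusted p under that level, limma-voom 0 with 6, and edgeR's exact test 0 with 2. Libraries of the groups did not overlap for 41 miRNAs, or 35.0%, where chance gives 33.3% for 2 libraries against 2. Infected libraries were the higher in 19 of these and the lower in 22. No miRNA at a mean of at least 10 CPM had a fitted log2 fold change above 1 in size, the largest of the 103 being 0.64, with a median SE of 0.17. That limit rests on single libraries: the largest was miR-2188 at −0.64, which stood at −1.05 without infected 1 and −0.33 without infected 2, and miR-2954 stood at −1.14 without non-infected 1 and 3.03 without non-infected 2.

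Of the miRNAs named for the smallest unadjusted edgeR p, miR-146c came first on the higher side, at 0.0197. It was followed by miR-182 (TTTGGCAATGGTAGAACTCACACT), with a log2 fold change of 0.52 ± 0.19 (SE) and unadjusted p of 0.0249, and by miR-146a (TGAGAACTGAATTCCATGGGTT), with 0.46 ± 0.20 and 0.0442. miR-218 (TTGTGCTTGATCTAACCATGT) and miR-31 (AGGCAAGATGTTGGCATAGCTG) had log2 fold changes of 0.34 ± 0.17 and 0.45 ± 0.23. On the lower side, miR-204 had an unadjusted edgeR p of 0.0210. The epithelial miR-200b (TAATACTGCCTGGTAATGATGA) followed with −0.36 ± 0.14 and 0.0312, then the neural miR-138 (AGCTGGTGTTGTGAATCAGGCCG) with −0.44 ± 0.19 and 0.0445. miR-2188 (AAGGTCCAACCTCACATGTCCT) and miR-193b (AACTGGCCCACAAAGTCCCGCT) had log2 fold changes of −0.64 ± 0.28 and −0.38 ± 0.17. None of these 10 miRNAs passed the threshold, with edgeR adjusted p from 0.746 to 0.836.

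**Figure D1:**
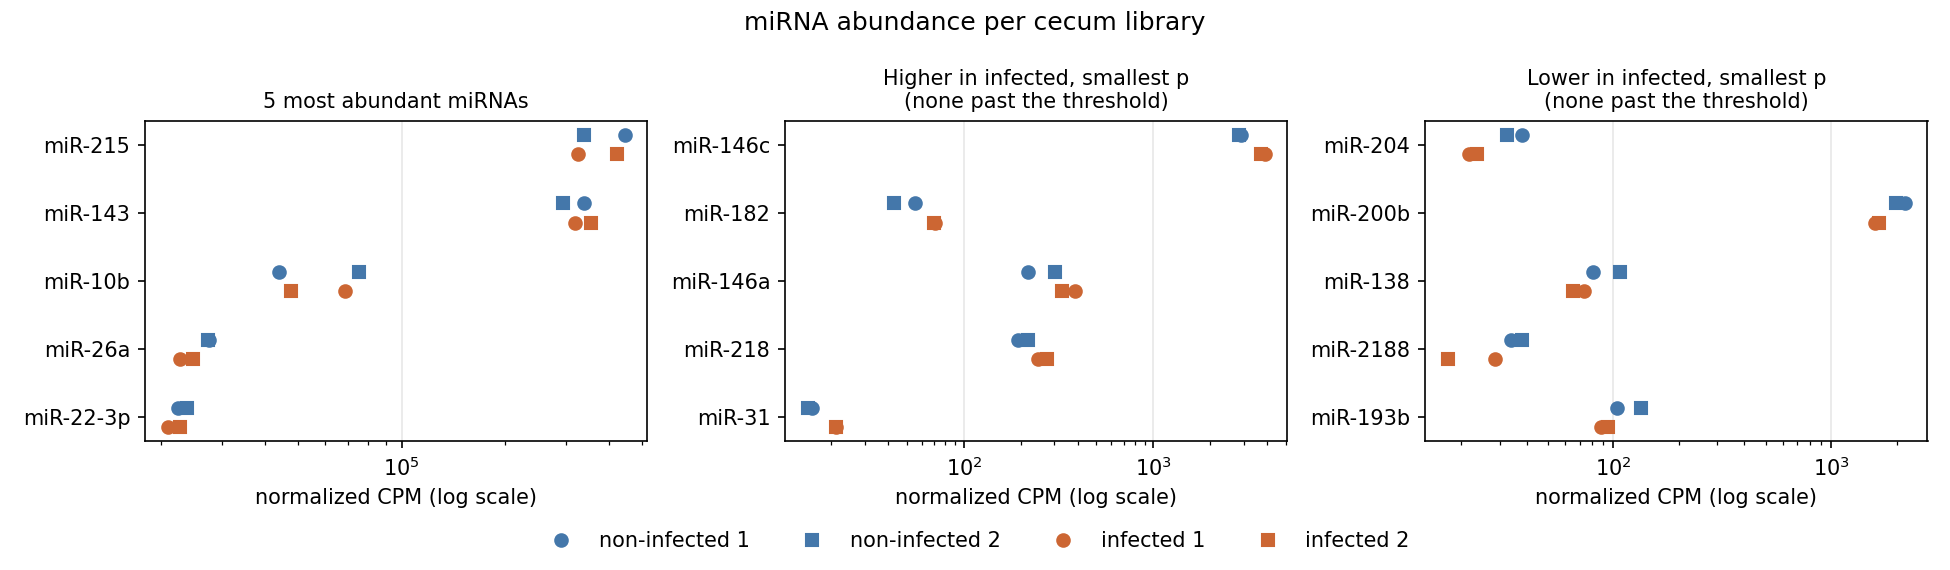
Normalized CPM (log scale) of each miRNA in each of the 4 libraries, for the 5 most abundant miRNAs and for the 5 with the smallest unadjusted p in each direction; circles are replicate 1, squares replicate 2, blue non-infected and orange infected. For miR-146c the infected libraries sit at 3875 and 3722 CPM against 2900 and 2830 CPM, while the groups overlap for miR-215, miR-143 and miR-10b; none of the miRNAs passed the threshold.

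Single libraries decided the calls that other fits made. Without non-infected 2, miR-2954 (CATCCCCATTCCACTCCTAGCA), a Z-linked and male-biased miRNA of birds, was called higher in infected cecum, with a log2 fold change of 3.03 and an edgeR adjusted p of 0.0473. With all libraries its log2 fold change was −0.19 ± 1.73 (SE); it stood at 105 CPM in non-infected 1 and 1863 CPM in non-infected 2 against 846 and 881 CPM in the infected libraries. Without infected 2, miR-122, abundant in liver, was called lower, with a log2 fold change of −2.13 and an edgeR adjusted p of 0.0202. Its level was 6.34 and 12.7 CPM in non-infected and 2.18 and 12.0 CPM in infected libraries.

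More miRNAs were called in a split of the 4 libraries that crosses the groups as labelled than between the groups. This split was not among the planned comparisons. Set against non-infected 1 and infected 2, the libraries non-infected 2 and infected 1 were higher in miR-145 by 1.33 ± 0.17 (log2, SE), in miR-19a by 1.34 ± 0.27, in miR-19b by 1.25 ± 0.20 and in miR-10b by 0.65 ± 0.11. They were lower in miR-215, at −0.38 ± 0.074. These 5 miRNAs passed the threshold by edgeR, with adjusted p from 2.91e-11 to 2.30e-05. Each split had a fit of its own. At these ratios of change to SE, the median of 7.30 prior degrees in the labelled fit would give larger p. The 5 calls here and 0 by the labels thus come from tests with unequal prior degrees. In the remaining split, replicate 2 against replicate 1, miR-122 was the 1 miRNA called.

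**Figure D2:**
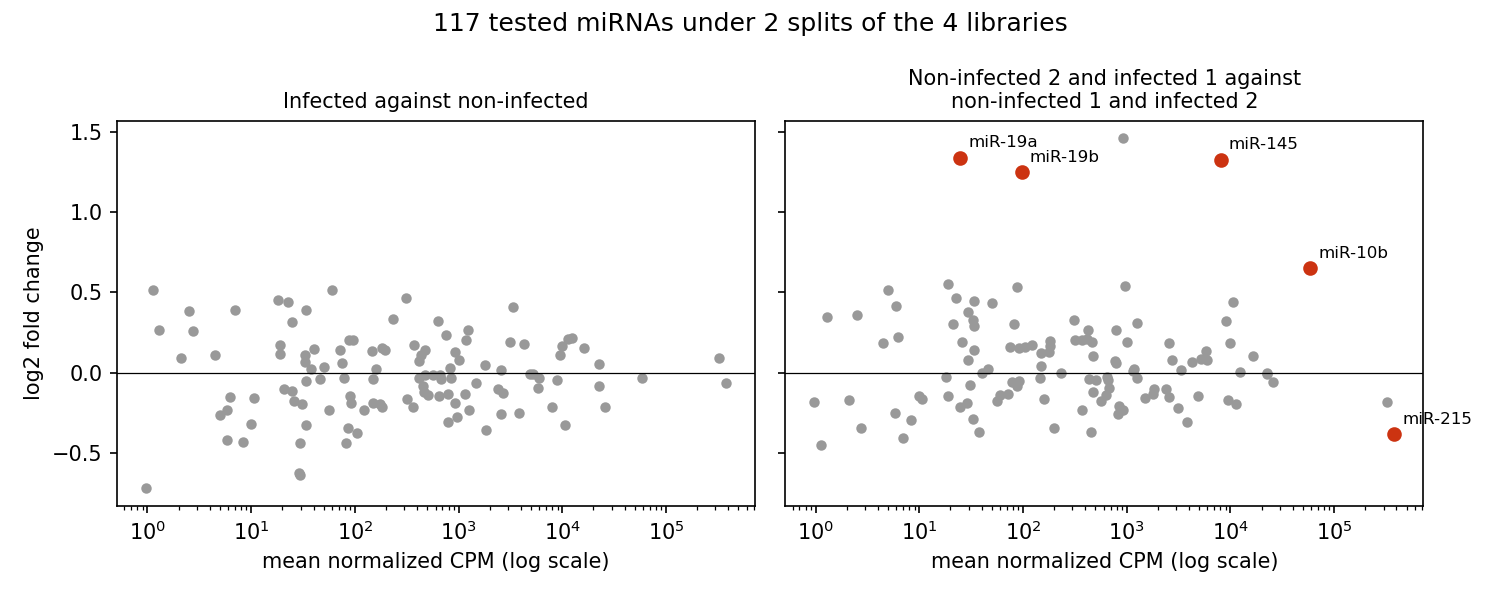
Log2 fold change against mean normalized CPM (log scale) for 117 miRNAs, for infected against non-infected libraries (left) and for non-infected 2 and infected 1 against non-infected 1 and infected 2 (right); each point is a miRNA and red points are past an adjusted p of 0.05. The left panel has 0 red points and the right panel 5, with miR-145 at 1.33 and miR-215 at −0.38.

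No group of miRNAs separated infected from non-infected cecum. Of 16 tested miRNAs tied to Toll-like receptor or NF-kB signalling, 8 were higher and 8 lower in infected libraries. Among them miR-21 had a log2 fold change of 0.053 ± 0.16 (SE), miR-125b −0.23 ± 0.21 and miR-146b 0.32 ± 0.25. Values of miR-146c and miR-146a are given above. Leukocyte miRNAs were split 4 to 2, with miR-181a at 0.15 ± 0.16, miR-181b at 0.080 ± 0.16 and miR-142-5p at −0.21 ± 0.21. Intestinal epithelial miRNAs were split 5 to 4, with miR-194 at 0.21 ± 0.16 and miR-429 at −0.25 ± 0.18. Smooth muscle and stromal miRNAs were split 4 to 7, with miR-143 at 0.091 ± 0.21, miR-10b at −0.036 ± 0.30 and miR-145 at −0.22 ± 0.86.

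Across the 15 lists of miRNAs fixed beforehand, 0 members were called over all miRNAs tested and 0 when adjusted over the list alone. The smallest p adjusted over the list alone was 0.213, for the neural list, in which 3 members were higher and 3 lower, with miR-128 at a log2 fold change of −0.016 ± 0.17 (SE). For the 9 lists with at least 3 tested members, limma's camera with a preset correlation of 0.01 gave adjusted p from 0.818 to 0.878, and with an estimated correlation none was below 0.974. For the immune list the median log2 fold change was −0.0053, the mean 0.052 and the camera direction upward. By fry, which asks whether a list's miRNAs change in either direction, the neural list had a mixed p of 0.00697 and an adjusted p of 0.0628. Without non-infected 1 the let-7 family was called higher by camera at the preset correlation, with a median log2 fold change of 0.12 over 8 members. Without non-infected 2 that median was −0.16. With a library left out, too few libraries remain to estimate the correlation, so camera with an estimated correlation cannot decide on the call.

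The remaining lists were also balanced or small. let-7 miRNAs were split 4 to 4, with let-7f at a log2 fold change of 0.11 ± 0.15 (SE), let-7a at −0.0080 ± 0.16 and let-7i at 0.015 ± 0.15. The miR-17-92 cluster and its paralogs, high in dividing cells, were split 3 to 6, with miR-92 at 0.17 ± 0.17, miR-17-5p at −0.20 ± 0.16 and miR-20a at −0.038 ± 0.16. The miR-30 family was split 3 to 4, with miR-30d at −0.045 ± 0.18, miR-30e at −0.094 ± 0.17 and miR-30a-5p at −0.0087 ± 0.15. Striated muscle miRNAs were split 2 to 2, with miR-133a at −0.042 ± 0.17, miR-1b at 0.20 ± 0.16 and miR-1a at −0.036 ± 0.17. Red cell miR-451 stood at −0.34 ± 0.24 and miR-144 at 0.38 ± 0.43, endothelial miR-126-5p at 0.18 ± 0.15 and miR-126-3p at 0.17 ± 0.18. The hypoxia-induced miR-210 stood at 0.14 ± 0.19, the p53-responsive miR-34a at −0.23 ± 0.19 and hepatic miR-122 at −0.43 ± 1.07.

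No difference in the balance between the arms of a miRNA hairpin was detected between the groups. Reads of the 5p arm made up 96.8% and 94.1% of miR-142 reads in non-infected libraries and 93.4% and 95.5% in infected libraries. For miR-199 they made up 12.2% and 16.2% against 13.1% and 10.7%. Of 7 hairpins tested with edgeR, 0 passed the threshold and 0 had an unadjusted p under 0.05; the smallest unadjusted p was 0.0853, for miR-142, with a log2 fold change of −0.39 in the ratio of 5p to 3p. The change for miR-199 was −0.31 and for miR-140 0.27. Most reads of the miR-140 3p arm began 1 base upstream of the sequence counted, and with these included the miR-140 change was −0.0056.

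Ends of tRNAs, and tags of 30 to 38 nt, of 50 nt and under 18 nt, varied between libraries without following infection. The 5′ ends of 6 tRNAs made up 0.147% and 0.719% of reads in the non-infected libraries and 0.600% and 0.280% in the infected libraries. Tags of 30 to 38 nt made up 0.155% and 1.40% against 1.10% and 0.252%, and tags of 50 nt 0.0522% and 0.0127% against 0.00679% and 0.0387%. At the single length of 18 nt both infected libraries were the higher, with 0.199% and 0.245% against 0.287% and 0.283%. At 19 nt they were also the higher, with 0.389% and 0.427% against 0.460% and 0.480%. At 44 nt and 47 nt both infected libraries were the lower. Non-infected 1 stood apart in tags under 18 nt, which were 0.000268% of its reads and 0.0343% to 0.0450% of the others. Of the 20 tags that it lacked and each of the other libraries held at 50 or more reads, 19 were under 17 nt. With 2 libraries per group, an exact two-sided permutation test cannot give a p below 0.333.

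**Figure D3:**
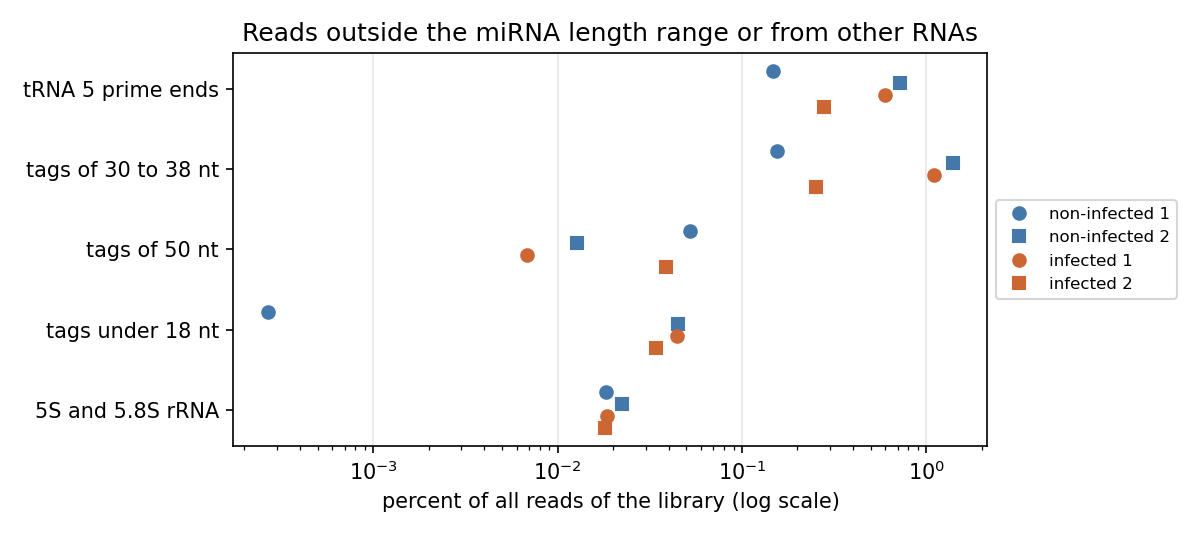
Percent of all reads of each library (log scale) in tRNA 5′ ends, tags of 30 to 38 nt, tags of 50 nt, tags under 18 nt and 5S or 5.8S rRNA; circles are replicate 1, squares replicate 2, blue non-infected and orange infected. Non-infected 2 and infected 1 lie highest in tRNA 5′ ends, at 0.719% and 0.600%, and non-infected 1 lies lowest in tags under 18 nt, at 0.000268%.

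The labels did not say that the libraries of a group came from separate birds, so that p-values measure the spread between these 4 libraries, which may be technical. In simulated counts for these miRNAs, the edgeR test called 11.2% of 1.5-fold, 41.9% of 2-fold and 94.4% of 4-fold changes. Over 20 sets of 117 miRNAs there were 160 changes of each fold, present together. Counts were drawn independently from the fitted dispersions, without the structure that crosses the groups. The shares called depend on how many miRNAs change and do not give the power for a few changed miRNAs.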

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

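The tests in this part were chosen after the result was seen, except that of Z-linked miRNAs. Reads from conserved sites of bacterial 16S rRNA, in data outside the miRNA comparison, were more frequent, in CPM of all reads, in both infected than in both non-infected libraries at 5 of 6 sites. All sites together gave 15.8 and 49.5 CPM in the non-infected libraries (exact 95% binomial intervals 14.1 to 17.7 and 46.0 to 53.2) and 191 and 38.7 in the infected libraries (184 to 198 and 35.6 to 41.9), so that the sum did not separate the groups. The exact permutation p cannot fall below 0.333, and the sites are shared by most bacteria and identify no species.

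One technical explanation for the bacterial reads is that some libraries kept longer fragments. Tags of 30 to 38 nt were most frequent in non-infected 2 and infected 1, but tags of 50 nt in non-infected 1 and infected 2. Over the 4 pairs of an infected and a non-infected library, the ratio of 16S reads was at least 1.50 times the ratio of tags of 30 to 38 nt, but single sites went below it in 4 of 24 cases, so that this cannot be told apart from a difference in bacteria. Another is that infected 1 carries the difference alone: infected 2 was above both non-infected libraries beyond counting error (exact binomial) at 2 of the 6 sites, too few to decide. More bacterial RNA in the infected cecum may also account for it, and stays open as an untested hypothesis.

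The libraries non-infected 2 and infected 1 stood apart from the others in 5 miRNAs, a structure that crosses the groups as labelled. Tag lengths paired the same way at 23 nt, with 7.77% and 7.76% of reads against 5.73% in non-infected 1 and 6.05% in infected 2. At 21 nt the pair was the lower, with 23.5% and 24.8% against 27.1% and 26.5%. Tags of 18 nt and 19 nt did not pair so. The relation of tag length to the 5 miRNAs was not tested. The smooth muscle and stroma list as a whole did not rise like miR-145, with a median log2 difference of 0.16 (SD 0.44 over 11 miRNAs) against 1.33. But miR-145 is on that list and was picked as its largest change. The comparison therefore cannot decide whether these libraries held more muscle wall. A library step that favours some sequences, such as ligation, cannot be told apart from turnover of single miRNAs: miR-145, miR-19a and miR-19b stood at least 1.13 ± 0.28 (log2, SE) from miRNAs of the same primary transcript, but were picked as called where those were not. Exchanged labels between the groups, under which infection would give this structure, cannot be told apart either. The split across the groups called 5 miRNAs and the split by the labels 0, from fits with unequal prior degrees. None of the tested miRNAs marks infection independently of the labels. The 16S reads, which identify no species, were higher in both infected libraries at 5 of 6 sites. Their sum was instead higher in non-infected 2 and infected 1 (49.5 and 191 against 15.8 and 38.7 CPM).

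miR-2954 differed 17.8-fold between the non-infected libraries, a log2 difference of 4.15, against at most 1.44 for the other 102 miRNAs at 10 CPM or more. The structure that crosses the groups does not account for it, since infected 1 and infected 2 differed by −0.058. Whole tags removed from the file of non-infected 1 are argued against as well, as all 8 distinct tags counted for miR-2954 were seen there. Their presence does not show that their counts were kept. The share of miR-2954 reads at another start was 1.65% there against 0.420% to 0.521% in the others. Male and female birds in different shares are a candidate explanation, as miR-2954 is male-biased. The median of the other Z-linked miRNAs, 3 in number, was 0.23 (log2) above that of the remaining miRNAs in non-infected 2 relative to non-infected 1. The SE of the mean over these 3 miRNAs was 0.13. Of them miR-24 and miR-27b differed by 0.26 and 0.37, and miR-31 by −0.069. These are too few to decide, and the labels give no sex.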

How the results depend on the processing

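Tag-matching alternatives, the crossed pairing and the tag groups were chosen after the data were seen. The count of 0 called miRNAs at an adjusted p under 0.05 held under each normalization, filter, tool and matching tried, and with the replicate block (0 calls, 2 at an unadjusted p under 0.05); it ran from 0 to 1 with each library left out, where a lone library is assumed to vary like the other group. At an adjusted p under 0.1 it was 0 with the original matching and 1 with exact mature sequences only, where miR-204 had a log2 fold change of −0.85 and an edgeR adjusted p of 0.0975, against 0.746. With the crossed pairing as block, 0 miRNAs were called, 15 had an unadjusted p under 0.05 and 4 an adjusted p under 0.1, and lists and arm usage gave 0. Lists past the threshold were 0 throughout, the replicate block and the estimated correlation included, and 0 to 1 with a library left out; arm usage gave 0 in every fit. Same-numbered libraries had deviations correlated at r = −0.094 across 117 miRNAs. This gives no sign of a shared step, but 4 libraries cannot exclude one, and the labels do not say what the number means. For the 3158 tag groups, miRNA tags included, r was −0.52. Called groups were 0 by edgeR (97 at an unadjusted p under 0.05), 7 by DESeq2 and 89 with the crossed pairing as block. With a library left out, called groups ran from 0 to 136 (2 without infected 1, 136 without infected 2). The cause was not tested. The edgeR test called 9 of 100 simulated 4-fold and 73 of 100 simulated 16-fold changes of tag groups.

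Among 44 named miRNAs, 0 passed the threshold in 525 fits with all libraries, the crossed pairing left out, and 2 did with a library left out; the sign changed in 27 of the 525, for 12 miRNAs. The cause was not tested, and most of these log2 fold changes were near 0. With upper-quartile factors they were miR-10b 0.092, miR-133a 0.032, miR-1a 0.038, miR-128 0.061, let-7a 0.060, miR-20a 0.051, miR-30d 0.055, miR-30a-5p 0.075 and miR-2954 0.0015. With exact mature sequences only they were miR-194 −0.017, miR-1a 0.18, let-7i −0.12, miR-30d 0.0052, miR-30e 0.12 and miR-30a-5p 0.19. With a 5′ shift allowed they were miR-133a 0.020, miR-128 0.0076, let-7a 0.013, miR-30a-5p 0.015 and, for the 5p to 3p ratio, miR-140 −0.0056. Summed over shared starts they were miR-128 0.0071, let-7a 0.013 and miR-30a-5p 0.014. Without a count filter they were let-7a 0.0026 and miR-30a-5p 0.0023, with library totals miR-30a-5p 0.0015, and for miR-2954 0.96 with the replicate block and 0.95 with limma-voom.

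With each library left out, the log2 fold changes that changed sign ranged from −0.27 to 0.12 for miR-215, −0.017 to 0.17 for miR-143, −0.40 to 0.39 for miR-10b, −0.54 to 0.10 for miR-125b, −0.060 to 0.20 for miR-181b, −0.47 to 0.062 for miR-142-5p, −0.23 to 0.80 for miR-144 and −0.94 to 0.67 for miR-145. They ranged from −0.16 to 0.065 for miR-133a, −0.14 to 0.032 for miR-1a, −0.0065 to 0.33 for miR-126-3p, −0.10 to 0.061 for miR-128, −2.13 to 0.34 for miR-122, −0.15 to 0.11 for let-7a, −0.13 to 0.14 for let-7i, −0.063 to 0.39 for miR-92 and −0.18 to 0.072 for miR-20a. For miR-30d they ran from −0.31 to 0.17, for miR-30e −0.29 to 0.073, for miR-30a-5p −0.14 to 0.11, for miR-210 −0.13 to 0.37, for miR-2954 −1.14 to 3.03, and for the 5p to 3p ratios of miR-142 −0.82 to 0.085 and of miR-140 −0.025 to 0.60. In all, 21 of the 44 named miRNAs, the 10 with the smallest p among them, changed sign in no fit, but leaving out a library moved 16 of these 21, and 6 of the 10, by over 1.5 times. The 6 were miR-182 (0.34 to 0.68), miR-146a (0.22 to 0.71), miR-218 (0.22 to 0.42), miR-138 (−0.65 to −0.23), miR-2188 (−1.05 to −0.33) and miR-193b (−0.58 to −0.19). Wide ranges were also those of miR-429 (−0.50 to −0.040), miR-451 (−0.64 to −0.073) and the miR-199 arm ratio (−0.53 to −0.062). Over all tags, not miRNAs alone, the 5 most abundant took 79.9%, 74.4%, 75.0% and 78.8% of reads in the 4 libraries.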

Other observations

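Most abundant miRNAs of the cecum began at the base they were counted by, and a few did not. Of 66 miRNAs with a mean of at least 1000 reads, 10 had over 10% of their reads starting 1 or 2 bases away, 2 had over 50%, and 33 had under 1%, with a median of 1.10%. miR-140-3p was the extreme, with 98.9% ± 0.047 of its reads at another start in non-infected libraries (mean ± SD, n = 2) and 99.1% ± 0.072 in infected libraries, most of them 1 base upstream. For miR-101 the share was 69.3% ± 1.60 and 67.3% ± 0.787, for miR-214 46.9% ± 4.10 and 49.5% ± 0.819, and for miR-199-3p, which is abundant in mesenchymal cells, 38.2% ± 0.458 and 39.4% ± 0.841. The 5′ base sets the seed by which a miRNA finds its targets; no test between the groups was run on these shares. They depend on the sequences chosen for counting, which were not taken from a chicken reference.

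Among tRNA fragments, the 5′ end of tRNA-Glu-CTC was the most frequent in each library, at 0.106% and 0.305% of reads in the non-infected and 0.252% and 0.203% in the infected libraries. That of tRNA-Gly-GCC varied more, from 0.0148% and 0.215% in the non-infected to 0.215% and 0.0362% in the infected libraries, and that of tRNA-Lys-CTT from 0.0106% and 0.135% to 0.0858% and 0.0186%.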
